A study of Mus musculus with 48 samples.

How the data were processed

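RNA abundance was measured on Affymetrix MG-U74Av2 arrays in ectoderm and mesoderm separated by trypsin from the right forelimb buds of mouse embryos. Dams were injected on gestation day 9.5 with cadmium sulfate at 4 mg/kg, with its vehicle phosphate-buffered saline (PBS), with acetazolamide at 400 mg/kg, or with its vehicle vegetable oil. Limb buds were taken 3 h or 12 h later, and buds of several litters were pooled for each RNA sample. The 2 agents and 2 vehicles, 2 tissues and 2 times made 16 groups of 3 arrays, 48 arrays in all.

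The values deposited by the authors are a ratio of each array to vehicle arrays of the same tissue and time, not an expression level, and the labels do not describe how it was made. In each of the 8 agent comparisons, vehicle arrays 1 and 2 summed to 2 for all 12488 probe sets (largest deviation 3e-07) and vehicle array 3 was 1 (largest deviation 6e-08). The first 2 vehicle arrays were thus divided by their own mean and the third by itself. That treated arrays 1 and 2 shared the first denominator and treated array 3 the second is an inference from the numbering, and the values bear it out only in part. A shared denominator sets a covariance between arrays, and the observed covariance lay below that value in 4 of 8 comparisons for treated arrays 1 and 2, in 5 for arrays 1 and 3 and in 7 for arrays 2 and 3. In 12 h cadmium ectoderm it was -0.00855 for arrays 1 and 2 and 0.0874 for arrays 1 and 3, where sharing gives 0.0558. The block below and the splits of the closing section rest on this inference, and counts without the block are given there. Because no level was kept, the planned comparisons of tissues, times and vehicles in untreated embryos could not be made, and neither could a filter on dim probe sets, a pseudocount, an intensity trend, quantile normalization or a choice of the brightest probe set. How far signal stood above background is unknown, and the number of arrays limits the precision.

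Ratios were converted to log2. Of the probe sets, 10855 named 1 gene, 396 named several and 1237 none. Probe sets naming 1 gene were averaged per gene, giving 8251 genes, of which 2073 had more than 1 probe set. Symbols were checked through Entrez identifiers for 10839 probe sets, and 0 changed. The 1633 probe sets without a single gene were tested separately.

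The model was fitted to all 48 arrays with limma 3.58.1 in R 4.3.3, with 16 means for the denominators (array pairs 1 and 2, and array 3, of each comparison), 8 agent effects and 24 residual degrees of freedom. Standard errors were moderated by eBayes without a trend. Benjamini-Hochberg adjustment ran over the genes of each comparison with a threshold of 0.05, and intervals are at 95%. Each agent effect is the log2 difference between treated and vehicle arrays. Differences of agent effects between agents, tissues and times were tested in the same model. The labels do not say that an array number marks a shared pool, and the model treats all arrays as independent. Correlations of the difference between arrays 1 and 2 over 24 pairs of groups ran from -0.44 to 0.65, and 8 of the 24 exceeded 0.1. Between ectoderm and mesoderm of the same group, 4 of 4 exceeded 0.1 in the acetazolamide arm (0.13 to 0.57) and 0 of 4 in the cadmium arm (-0.31 to 0.0924). Whether both tissues came from the same pools is not known, so the closing section also gives mean effects on tissue averages.

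The design, the alternatives, the gene lists and the rule for named genes were set before the data were examined. The design set then had 1 shared spread and no denominator block. The block was added because of the vehicle ratios. Arrays of each comparison were also given 1 precision weight, from the median residual variance of its 6 arrays, because the residual SD ran from 0.115 in the 12 h cadmium mesoderm comparison to 0.223 in the 12 h cadmium ectoderm comparison. The weights were chosen after counts without weights had been seen and before weighted counts were seen, and the choice rested on simulated data. There, changes added to noise drawn independently for each gene gave 4.98% false calls with weights (71 of 1427) and 16.3% without (265 of 1623). The noise of each comparison was scaled by these same weights, so the simulation favoured them by construction and could not test them. Counts without weights and from the original design are in the closing section.

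The 29 gene lists, of pathways and of cell type markers, were tested in each agent comparison with limma camera at a preset correlation of 0.01, adjusted over the 29 lists. Camera, which tests a list against the other genes, was also run with a correlation estimated from the data. Limma fry, which tests a list against no change, stood beside it. The pathway lists covered metallothionein and metal transport, oxidative stress, heat shock, unfolded protein and amino acid stress, p53 targets, hypoxia and glycolysis, carbonic anhydrases and pH transport, the Hedgehog, BMP, Wnt and retinoic acid pathways, FGF feedback targets, apical ridge and limb ectoderm patterning, Hox and limb mesoderm patterning, chondrogenesis and matrix, mitosis, DNA replication, cholesterol synthesis, the immediate early response, glucocorticoid-responsive genes and the interferon response. The marker lists covered surface ectoderm, limb mesoderm, red blood cells, endothelium, muscle progenitors, neural crest with neurons, macrophages with other white blood cells, and endoderm.

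Genes are named by rule: up to 6 called genes in each direction with the largest change and separate treated and vehicle arrays; up to 4 called members of each pathway list by smallest p; 10 genes in every comparison whatever the result (Mt1, Mt2, Hmox1, Shh, Ptch1, Gli1, Fgf8, Fgf10, Cdkn1a and Car2); up to 8 genes called under both agents; and up to 4 genes with the largest called difference between agents, and between tissues or times. Other named genes were chosen after their values were seen, as called markers, as examples of a list or as members passing over the list alone. In the report these are Slc30a1, Btg2, Tpi1, Aldoa, Tie1, Eng, Alas2, Nek2, Kif11, Anln, Ccna2, Cenpa, Wnt6, Cldn7, Msmo1, Id1, Id2 and Hoxd9.

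Alternatives planned beforehand were leaving out each array in turn, a replicate block, limma arrayWeights, a fit of only the arrays compared, rank correlation, and both other list tests. Alternatives chosen after seeing the data were no weights, the original design, the weights without the denominator block, arrays centred on their median, a covariate for the main axis of difference between vehicle arrays (39.4% of the variance of the 8 differences between vehicle arrays 1 and 2), only the first and second arrays, leaving out both arrays with the highest Gapdh 3' to 5' ratio, and probe sets tested separately. For mean effects they also included ectoderm and mesoderm averaged within each array number, and the mean of the Gapdh and actin 3' to 5' ratios as a covariate. Mean effects over several comparisons were also added after seeing the data. Figures were drawn with matplotlib 3.10.9.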

Results

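The 48 arrays held 12488 probe sets and covered 16 groups of 3. Each of 8 comparisons set 3 arrays from embryos of treated dams against 3 arrays from embryos of dams given the vehicle, in limb bud ectoderm or mesoderm, at 3 h or 12 h. The values are ratios to vehicle arrays, so vehicle arrays lie around 0 on the log2 scale by construction. The medians of single arrays ran from -0.12 to 0.10 in log2 ratio. The median width of a gene's 95% interval to either side was 0.21 in the 12 h cadmium mesoderm comparison and 0.42 in the 12 h cadmium ectoderm comparison, the narrowest and the widest of the 8. Changes below are log2 differences between treated and vehicle arrays with their SE, and n = 3 arrays in each group.

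The series addresses 2 teratogens that produce a similar forelimb defect. The first question is which genes each agent changed in each tissue and at each time. At 12 h after cadmium, limb bud mesoderm had more RNA of p53 target genes and less metallothionein RNA than mesoderm of vehicle-treated dams. Ccng1, which encodes cyclin G1, rose by 1.94 ± 0.27, a 3.83-fold change (adjusted p = 6.52e-05). Cdkn1a, the cell cycle inhibitor p21, rose by 1.57 ± 0.20 (adjusted p = 4.86e-05), and Phlda3, a repressor of Akt signalling, rose by 1.53 ± 0.20. Zmat3, an RNA-binding zinc finger gene, rose by 0.90 ± 0.12. Mt2, which encodes a metal-binding metallothionein, fell by 2.86 ± 0.21, a 7.25-fold change (adjusted p = 6.68e-10). The treated arrays averaged -2.92 ± 0.38 in log2 ratio (SD, n = 3) for Mt2 and the vehicle arrays -0.06 ± 0.51. These SDs describe the ratios and not 3 free samples, because the denominators tie vehicle arrays 1 and 2 together and fix array 3 at 0. For each of these 5 genes all 3 cadmium arrays lay beyond all 3 vehicle arrays. The rule that names genes with the largest change asks for separate arrays, so this is no further support.

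In all, 188 of 8251 genes passed the threshold in 12 h cadmium mesoderm, of which 87 rose and 101 fell (1143 at an unadjusted p under 0.05). In 184 of the 188 the treated and vehicle arrays were fully separate, but a call itself selects genes with a large difference. Of all genes 19.3% were separate, where chance gives 10% for independent arrays and simulated noise with these denominators gave 13.4%. The share was 5.90% to 16.8% in the other 7 comparisons. Among the largest changes, Dpysl4 rose by 0.91 ± 0.13 and Pfkp, the platelet-type phosphofructokinase of glycolysis, by 1.05 ± 0.28. Uqcc3, an assembly factor of respiratory complex III, fell by 1.29 ± 0.19, Ogt, the enzyme that adds O-linked N-acetylglucosamine to proteins, by 1.10 ± 0.18, and the splicing factor gene Rbm25 by 1.06 ± 0.23. Zscan26, a zinc finger gene, fell by 1.06 ± 0.19 and the kinase gene Nek7 by 0.99 ± 0.13. The count was 58 without PBS array 3, the same without cadmium array 3, 99 without cadmium array 2 and 361 without cadmium array 1. It was 22 without weights and 0 in limma on these 6 arrays alone (988 at an unadjusted p under 0.05).

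Of 15 measured p53 targets, 4 rose after 12 h of cadmium in mesoderm (the 4 above) and 5 adjusted over the list alone, the fifth being Btg2 at 0.26 ± 0.08. The list as a whole was higher (camera adjusted p = 1.93e-05, and adjusted p = 0.000550 with an estimated correlation). Of 12 measured genes of metallothionein and metal transport, 2 fell, Mt2 and Mt1 (-0.76 ± 0.14, adjusted p = 0.00204), and 3 adjusted over the list alone, the third being the zinc exporter gene Slc30a1 at -0.22 ± 0.06. That list was lower (adjusted p = 0.00358, and adjusted p = 0.0174 with an estimated correlation). These are the 2 of 27 list calls over the 8 comparisons that held with an estimated correlation. Mt1 and Mt2 lie side by side on chromosome 8 (GRCm38), Mt2 from 94172618 to 94173567 and Mt1 from 94178883 to 94180327. Cdkn1a, on chromosome 17 from 29090979 to 29100722, had 2 probe sets with differences of 2.58 and 0.55. Ccng1 lies on chromosome 11 (40748552 to 40755309), Phlda3 on chromosome 1 (135766085 to 135769134) and Zmat3 on chromosome 3 (32334792 to 32365665). The Mt1 call was lost without weights, with adjusted p = 0.121 (6.21e-05 to 0.155 over its alternatives).

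**Figure D1:**
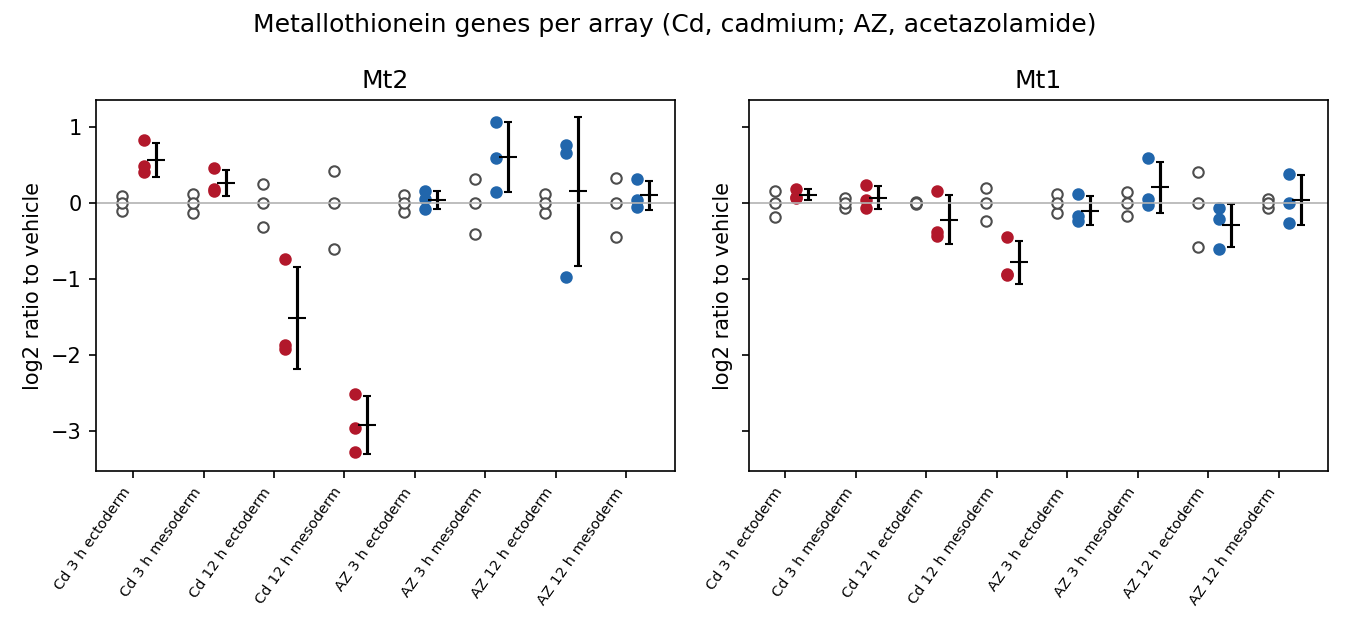
Log2 ratio to vehicle (vertical axis) of Mt2 and Mt1 in each array of the 8 agent comparisons, with vehicle arrays as open circles, cadmium arrays as filled red circles, acetazolamide arrays as filled blue circles, and the mean and SD of the 3 treated arrays as a dash and bar. In 12 h mesoderm the 3 cadmium arrays of Mt2 averaged -2.92 and all lay below the 3 vehicle arrays.

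**Figure D2:**
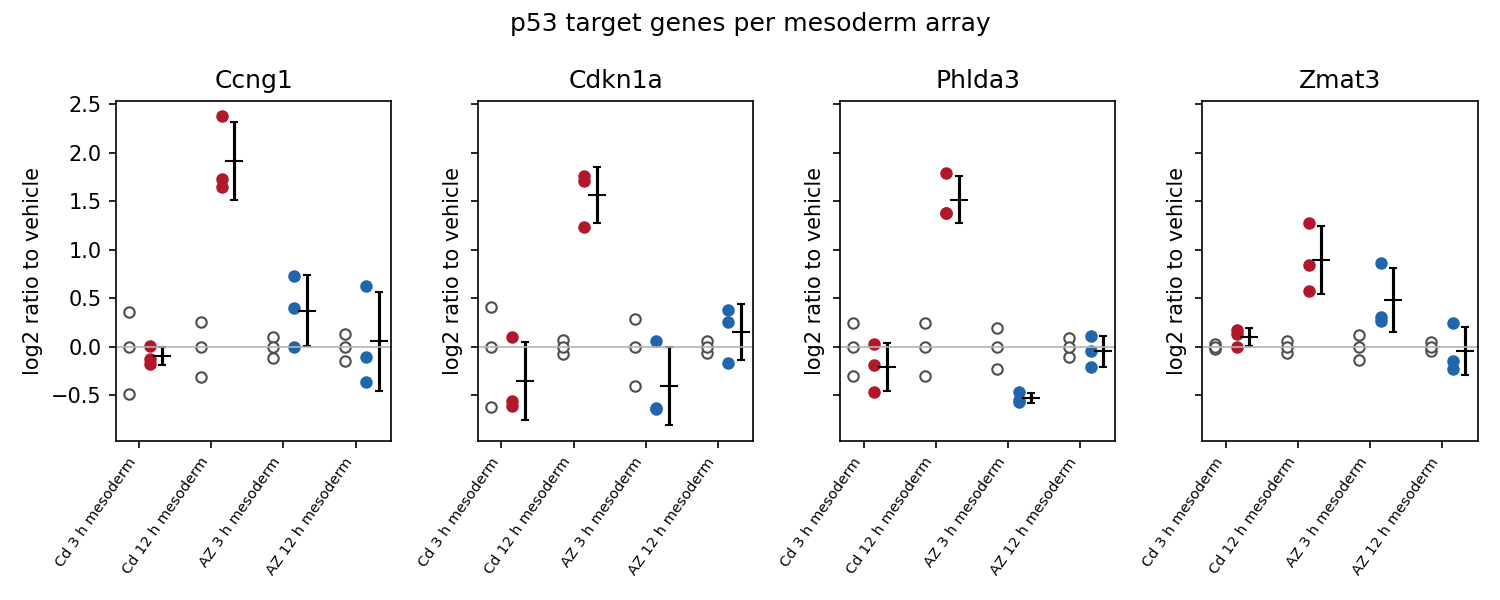
Log2 ratio to vehicle (vertical axis) of Ccng1, Cdkn1a, Phlda3 and Zmat3 in each array of the 4 mesoderm comparisons, with vehicle arrays as open circles, cadmium arrays in red, acetazolamide arrays in blue, and the mean and SD of the 3 treated arrays as a dash and bar. At 12 h after cadmium the treated arrays of all 4 genes lay above the vehicle arrays, with means of 1.92 for Ccng1, 1.57 for Cdkn1a, 1.52 for Phlda3 and 0.90 for Zmat3.

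Of 28 measured genes of hypoxia and glycolysis, 2 rose at 12 h after cadmium in mesoderm, Pfkp and Pfkl (0.83 ± 0.18), and 4 adjusted over the list alone, Tpi1 and Aldoa being the others. The list was higher (adjusted p = 0.000294, but adjusted p = 0.561 with an estimated correlation). Of 22 oxidative stress genes, Gsta4 rose by 0.60 ± 0.16, and Gclc, the catalytic subunit of glutathione synthesis, fell by 0.35 ± 0.08. The same 2 passed over the list alone, and the list did not pass (adjusted p = 0.153 at its smallest over the 8 comparisons). Of 20 heat shock and chaperone genes, the mitochondrial chaperone gene Hspd1 fell by 0.24 ± 0.07 and was 1 over the list alone. Ccnd1, which encodes cyclin D1 and stood in the Hedgehog list, fell by 0.34 ± 0.06. The glucocorticoid-responsive genes Mt1, Mt2 and Fkbp5 (-0.40 ± 0.10) were the 3 called of 20 measured, and 4 fell and 2 rose adjusted over the list alone. Calls of Pfkp (adjusted p = 0.544), Pfkl (0.122), Gsta4 (0.0765), Hspd1 (0.237), Fkbp5 (0.262), Zscan26 (0.0719) and Rbm25 (0.267) were lost without PBS array 3, and equally without cadmium array 3. The Pfkp call also ended without PBS array 2 (0.0774) or cadmium array 1 (0.0528), and the Pfkl call without cadmium array 2 (0.0575). Without PBS array 1 the calls of Fkbp5 (0.0691), Gsta4 (0.212) and Hspd1 (0.152) ended, and without cadmium array 2 those of Fkbp5 (0.172), Gsta4 (0.243) and Hspd1 (0.0983). The Hspd1 call ended without cadmium array 1 as well (0.0556). The calls of Gclc and Ccnd1 passed in every fit without 1 array. They ended without weights (0.416 and 0.121), in the original design (0.336 and 0.0734), with only the first and second arrays (0.112 and 0.0584) and with only the arrays compared (0.174 and 0.165). Over all alternatives the adjusted p ran from 0.00663 to 0.416 for Gclc, 0.000208 to 0.165 for Ccnd1, 0.00942 to 0.666 for Pfkp, 0.00330 to 0.427 for Pfkl, 0.009999 to 0.675 for Fkbp5, 0.0214 to 0.610 for Gsta4, 0.0271 to 0.587 for Hspd1, 2.10e-05 to 0.238 for Zscan26 and 0.00159 to 0.465 for Rbm25.

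Markers of other cell types moved alongside these groups in 12 h cadmium mesoderm. Of 15 measured endothelial markers, 2 rose, Tie1 (0.63 ± 0.12) and Eng (0.58 ± 0.16), both endothelial receptor genes, and 4 adjusted over the list alone. The endothelial list was higher (adjusted p = 0.000546, but adjusted p = 0.157 with an estimated correlation). Alas2, the erythroid enzyme of heme synthesis, was the 1 called of 18 red blood cell markers and rose by 0.53. The Gapdh 3' to 5' log2 ratio differed by -0.25 between treated and vehicle arrays, but by -0.0161 without cadmium array 1, -0.0770 without PBS array 2, -0.43 without cadmium array 2 and -0.42 without PBS array 1. The score on the vehicle axis differed by 5.71.

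At 12 h after cadmium, ectoderm had 2 called genes, with 367 at an unadjusted p under 0.05. Mcam, a cell adhesion gene of the immunoglobulin family, rose by 1.10 ± 0.16 (adjusted p = 0.000981), and Vps4a, an ATPase gene of endosomal sorting, fell by 1.09 ± 0.19 (adjusted p = 0.0213). Ccng1 was 1.80 ± 0.52, Cdkn1a 1.11 ± 0.38 and Mt2 -1.49 ± 0.41, with all 3 treated arrays beyond the vehicle arrays, but the 3 genes did not pass (adjusted p = 0.457, 0.758 and 0.439). Adjusted over the list alone, 4 of 15 p53 targets were higher and 1 lower, and 1 of 12 genes of metallothionein and metal transport was lower. Of 26 measured mitosis genes, 3 lay above 0 and 0 were called, over all genes or adjusted over the list alone. Examples are the kinase gene Nek2 at -0.93 ± 0.29 and the motor protein gene Kif11 at -0.93 ± 0.35. The mitosis list was lower with a median of -0.38 (adjusted p = 2.82e-08, but adjusted p = 0.0734 with an estimated correlation), as was the DNA replication list with a median of -0.20 (adjusted p = 0.0369, but adjusted p = 0.691 with an estimated correlation). The Gapdh 3' to 5' log2 ratio differed by 0.49, which rested on cadmium array 2 (1.80): the difference was -0.14 without it, 1.09 without cadmium array 1 and 0.31 without PBS array 1. On the vehicle axis the cadmium arrays stood 13.6 from the PBS arrays. The count was 0 without PBS array 3 or cadmium array 3, 1 without PBS array 2 or cadmium array 1, 90 without PBS array 1, 20 without cadmium array 2, and 89 without weights. The Vps4a call ended in the first 2 of these groups (adjusted p = 0.810, 0.119 and 0.265), and the Mcam call in the first (adjusted p = 0.403). Over all alternatives the adjusted p ran from 2.13e-06 to 0.951 for Mcam and from 1.19e-05 to nearly 1 for Vps4a.

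At 3 h after cadmium, 0 genes passed in limma in ectoderm (274 at an unadjusted p under 0.05) and 0 in mesoderm (256). Mt2 was 0.58 ± 0.26 in ectoderm and 0.27 ± 0.22 in mesoderm. In mesoderm, 3 lists passed with the preset correlation and not with an estimated one. Genes of the apical ridge and limb ectoderm were higher with a median of 0.21 (14 of 21 above 0, adjusted p = 6.33e-05, but adjusted p = 0.0855 with an estimated correlation), for example the ligand gene Wnt6 at 0.39 ± 0.17. Surface ectoderm markers were higher with a median of 0.13 (25 of 30 above 0, adjusted p = 2.05e-06, but adjusted p = 0.103 with an estimated correlation), for example the tight junction gene Cldn7 at 0.48 ± 0.17. Both lists hold ectoderm genes, measured here in mesoderm, and a difference in ectoderm left on the mesoderm was not tested. Cholesterol synthesis genes were lower with a median of -0.17 (2 of 18 above 0, adjusted p = 1.15e-06, but adjusted p = 0.0855 with an estimated correlation), for example Msmo1 at -0.58 ± 0.21. In ectoderm, surface ectoderm markers were also higher (median 0.12, adjusted p = 0.00144) and endoderm markers lower (median -0.07, adjusted p = 0.00685), with adjusted p = 0.663 and 0.850 with an estimated correlation. Without PBS array 2 the ectoderm count was 96, and without PBS array 1 the mesoderm count was 13.

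The next question is whether cadmium acted differently at 12 h than at 3 h, or in 1 tissue than in the other. In mesoderm, 38 genes differed between the times, 13 in the higher and 25 in the lower direction (712 at an unadjusted p under 0.05). The effect on Mt2 was lower at 12 h than at 3 h by -3.13 ± 0.30 (adjusted p = 4.41e-07). The effects on Ccng1 (1.99 ± 0.38), Cdkn1a (1.85 ± 0.28) and Phlda3 (1.73 ± 0.28) were higher at 12 h. In ectoderm 1 gene differed, Mcam (1.13 ± 0.19, adjusted p = 0.0111), with 288 at an unadjusted p under 0.05. Between the tissues, 0 genes passed in limma at 3 h (68 at an unadjusted p under 0.05) and 0 at 12 h (114). The median width of a gene's 95% interval to either side was 0.35 and 0.47 for these differences. Mt2 differed by 1.37 ± 0.46 between ectoderm and mesoderm at 12 h (95% interval 0.43 to 2.32) and did not pass. Of the 188 genes called in 12 h mesoderm, 175 (93.1%) had the same sign in ectoderm, against 67.0% of all genes, and 1, Vps4a, was called in both (0.0122 expected by chance among the genes that fell). Across genes, which are not independent replicates, the mesoderm and ectoderm effects had r = 0.57 at 12 h (Spearman's rho = 0.49) and r = 0.39 at 3 h (rho = 0.36). The mesoderm count of 38 was 5 without the 3 h cadmium array 1, 13 without the 3 h cadmium array 2, 17 without the 12 h cadmium array 2 and 7 without array 3 of either group at either time. It was 71 without the 3 h PBS array 1 or array 2, and 95 without the 12 h cadmium array 1. The Mcam difference did not pass without the 3 h cadmium array 2 (adjusted p = 0.0894) or array 3 of either 12 h ectoderm group (0.634). The Ccng1 difference did not pass without the 3 h cadmium array 1 (adjusted p = 0.105) or array 3 of either 3 h group (0.0954). Over all alternatives the adjusted p ran from 3.27e-05 to 0.739 for the Mcam difference and from 0.000180 to 0.599 for the Ccng1 difference.

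Acetazolamide, an inhibitor of carbonic anhydrases, changed few genes by the same test. In 3 h ectoderm 2 genes rose and 0 fell (564 at an unadjusted p under 0.05). They were Crebrf, a regulator of the unfolded protein response, at 0.93 ± 0.12 (adjusted p = 0.000188), and Cxadr, a tight junction receptor, at 0.72 ± 0.12 (adjusted p = 0.00736). In 3 h mesoderm 3 genes rose and 0 fell (607 at an unadjusted p under 0.05). They were Slc6a15, an amino acid transporter gene, at 0.86 ± 0.14 (adjusted p = 0.0107), Kyat3, a kynurenine aminotransferase gene, at 0.72 ± 0.13 (0.0390), and Atf6, a transcription factor of the unfolded protein response, at 0.52 ± 0.10 (0.0484). All 3 treated arrays lay above the vehicle arrays for these 5 genes. At 12 h, 0 genes passed in limma in ectoderm (649 at an unadjusted p under 0.05, smallest adjusted p = 0.0734) and 0 in mesoderm (65). The actin 3' to 5' log2 ratio was higher in acetazolamide than in oil arrays in each comparison, by 0.26 and 0.52 at 3 h in ectoderm and mesoderm and by 0.23 and 0.24 at 12 h. The Gapdh ratio was higher by 0.45 and 0.59, and by 0.41 and 0.42. In 12 h mesoderm the Gapdh difference rested on acetazolamide array 2: it was -0.20 without it, 0.15 without oil array 1, and 0.69 to 0.76 without oil array 2 or acetazolamide array 1 or 3. In 3 h mesoderm the actin difference was 0.19 without acetazolamide array 1, 0.23 without oil array 2, 0.35 without oil array 3, and 0.97 and 0.997 without acetazolamide array 3 and oil array 1. The Gapdh difference there was 0.38 without oil array 2. The 3 h ectoderm count was 78 without oil array 3 or acetazolamide array 3 and 5 without oil array 2. The 3 h mesoderm count was 0 without acetazolamide array 1 or array 2, 1 without array 3 of either group, and 141 without oil array 1. The Cxadr call ended without acetazolamide array 2 (adjusted p = 0.0543), the Slc6a15 call without acetazolamide array 1 (0.143) or 2 (0.486), and the Kyat3 and Atf6 calls without any of these or oil array 2 or 3 (0.0567 to 0.486 and 0.0762 to 0.999). Over all alternatives the adjusted p ran from 0.000177 to 0.729 for Cxadr, 0.000708 to 0.486 for Slc6a15, 0.000719 to 0.486 for Kyat3, 0.00354 to 0.999 for Atf6 and 0.000153 to 0.566 for Crebrf. The 12 h ectoderm count was 338 without oil array 2, 6 without array 3 of either group and 1 without oil array 1.

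Several lists moved after acetazolamide with the preset correlation, and 0 with an estimated one. In 3 h mesoderm the BMP pathway was lower (median -0.14, 4 of 23 above 0, adjusted p = 0.0120, but adjusted p = 0.136 with an estimated correlation). None of its members was called over all genes, and 2 were lower adjusted over the list alone, the BMP-responsive genes Id1 (-0.84 ± 0.25) and Id2 (-0.47 ± 0.15). Hox and limb mesoderm patterning genes were lower there too (median -0.15, adjusted p = 0.0177, but adjusted p = 0.419 with an estimated correlation), for example Hoxd9 at -0.58 ± 0.18. In 12 h ectoderm p53 targets were higher (median 0.32, adjusted p = 0.0373, but adjusted p = 0.295 with an estimated correlation), with Zmat3 at 0.70 ± 0.20 as the 1 gene passing over the list alone. Mitosis genes (median 0.23, adjusted p = 0.00205) and genes of hypoxia and glycolysis (median 0.16, adjusted p = 0.0294) were higher there, with adjusted p = 0.605 and 0.902 with an estimated correlation. Markers of endothelium (median -0.16, adjusted p = 0.0148), muscle progenitors (-0.15, 0.0148), white blood cells (-0.11, 0.00580) and endoderm (-0.17, 0.00205) were lower in the same arrays, each with adjusted p = 0.605 with an estimated correlation. These arrays stood -17.2 from their oil arrays on the vehicle axis, the largest distance of the 8 comparisons. In 12 h mesoderm, heat shock genes (median -0.12, adjusted p = 0.000352) and unfolded protein response genes (-0.05, 0.00795) were lower, each with adjusted p = 0.275 with an estimated correlation. Genes of hypoxia and glycolysis (0.16, adjusted p = 8.48e-05) and mitosis (0.07, 0.0248) were higher there, each with adjusted p = 0.695 with an estimated correlation. In 3 h ectoderm 0 of 29 lists passed.

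For differences of the acetazolamide effect between tissues, limma called 0 genes at 3 h (140 at an unadjusted p under 0.05) and 0 at 12 h (230). Between 12 h and 3 h it called 0 in ectoderm (261) and 0 in mesoderm (190). The median width of a gene's 95% interval to either side was 0.41 to 0.47 for these differences, so smaller differences are not excluded. Slc6a15, Kyat3 and Atf6 had the same sign in 3 h ectoderm as in mesoderm, as had 69.2% of all genes. At 12 h 50.7% of all genes had the same sign in both tissues. Across genes the effects in the 2 tissues had r = 0.52 at 3 h (rho = 0.47) and r = 0.18 at 12 h (rho = 0.08).

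The last question is whether the 2 agents acted alike. Calls could not be shared between the agents, because 1 agent had 0 called genes in limma in each tissue and time, cadmium at 3 h (274 and 256 at an unadjusted p under 0.05) and acetazolamide at 12 h (649 and 65). Mt2 in 12 h mesoderm differed between cadmium and acetazolamide by -3.00 ± 0.36 (adjusted p = 4.22e-05), as 1 called gene (325 at an unadjusted p under 0.05). Crebrf in 3 h ectoderm differed by -1.11 ± 0.16 (adjusted p = 0.00202), again as 1 called gene (517). In limma 0 genes passed in the agent difference of 3 h mesoderm (233 at an unadjusted p under 0.05) and 0 in that of 12 h ectoderm (963, smallest adjusted p = 0.0532). Cdkn1a differed by 1.41 in 12 h mesoderm, with a 95% interval from 0.72 to 2.10, and did not pass (adjusted p = 0.282). Across genes the effects of both agents had r = -0.16 in 3 h ectoderm (rho = -0.12), 0.28 in 3 h mesoderm (rho = 0.25), -0.46 in 12 h ectoderm (rho = -0.50) and 0.08 in 12 h mesoderm (rho = 0.06). The jackknife SE of r over arrays was 0.60, 0.42, 0.45 and 0.34, and the SE was larger than r itself in 3 of the 4 and about as large in 12 h ectoderm. Of the 188 cadmium genes of 12 h mesoderm, 114 (60.6%) had the same sign after acetazolamide, against 51.9% of all genes. The 12 h ectoderm count of the agent difference was 297 without weights.

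The genes named in every comparison include regulators of limb outgrowth. Shh, the signal of the zone of polarizing activity, its targets Gli1 and Ptch1, the ridge signal Fgf8, the mesodermal signal Fgf10, the heme oxygenase gene Hmox1 and the carbonic anhydrase gene Car2 were not called in any of the 8 comparisons. Fgf8 was -0.66 ± 0.23 in 3 h ectoderm after cadmium and 0.71 ± 0.31 in 12 h ectoderm after acetazolamide, with adjusted p = 0.999 and 0.621. Shh was -0.29 ± 0.14 in 12 h ectoderm after acetazolamide (adjusted p = 0.635). The 2 probe sets of Ptch1 had opposite signs in 7 of the 8 comparisons, for example -0.78 and 0.17 in 12 h cadmium ectoderm, so the averaged value says little about this gene. After acetazolamide, Mt2 was 0.63 ± 0.29 in 3 h mesoderm (adjusted p = 0.646), and Cdkn1a lay between -0.37 and 0.35 over the 4 comparisons.

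The lists not yet given passed in 0 of the 8 comparisons. Their smallest adjusted p was 0.691 for carbonic anhydrases and pH transport, 0.290 for the Hedgehog pathway, 0.0652 for FGF feedback targets, 0.205 for the Wnt pathway, 0.0832 for the retinoic acid pathway, 0.464 for chondrogenesis and matrix, 0.160 for the immediate early response, 0.0597 for glucocorticoid-responsive genes and 0.0997 for the interferon response. For markers it was 0.160 for limb mesoderm, 0.160 for red blood cells and 0.303 for neural crest and neurons. In 12 h cadmium mesoderm, heat shock genes (median -0.13, adjusted p = 0.0402), mitosis genes (-0.10, 0.0234) and cholesterol synthesis genes (-0.10, 0.0402) were also lower, with adjusted p = 0.561, 0.561 and 0.584 with an estimated correlation. Of the mitosis genes 0 were called over all genes and 4 were lower adjusted over the list alone, Anln, Nek2, Ccna2 and Cenpa. Over 232 list tests, camera passed 27 with the preset correlation and 2 with an estimated one. By fry, which tests a list against no change and not against the other genes, 5 passed.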

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

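The splits of arrays were planned, the test of the vehicle axis was chosen before its result was seen, and the tests of opposite action and of the Mt2 fall were chosen after the results were seen. The results in this part stand out because the effect of an agent differed between groups by a test of the difference itself.

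Between cadmium and acetazolamide, Crebrf differed by -1.11 in 3 h ectoderm and was the 1 gene called there. Mt2 differed by -3.00 in 12 h mesoderm and was likewise the 1 gene called. Both calls passed in every fit without 1 array and ended with only the arrays compared, and that of Crebrf also ended with only the first and second arrays (adjusted p = 0.265). The adjusted p ran over all alternatives from 2.23e-05 to 0.480 for Crebrf and from 4.96e-08 to 0.306 for Mt2. Over the 72 splits of the arrays within their denominators, 13 called at least as many genes in 3 h ectoderm (1 in the real split, 122 at the highest other) and 16 in 12 h mesoderm (1, and 32 at the highest other), so for these counts chance cannot be excluded. Some of these splits keep the real grouping of 1 comparison or turn its sign, and so carry an agent effect. The number of splits that match thus does not decide about chance. A count far above the real one may come from a kept agent effect or from a structure of the samples, which were not told apart. A count of 0 is matched by every split by definition, so with 0 genes called in limma all 72 splits called as many in 3 h mesoderm (233 genes at an unadjusted p under 0.05, highest other split 2) and in 12 h ectoderm (963, highest other 119).

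Between 12 h and 3 h after cadmium, 38 genes differed in mesoderm and 1 in ectoderm, Mcam at 1.13. In mesoderm the named genes with a lower effect at 12 h were Mt2 (-3.13), Uqcc3 (-1.27), Nek7 (-1.16), Atf6 (-0.53), Slc30a1 (-0.47) and Ccnd1 (-0.44). Among the genes with a higher effect were Ccng1 (1.99), Cdkn1a (1.85), Phlda3 (1.73) and Zmat3 (0.80). Mt2, Cdkn1a, Phlda3 and Nek7 passed in every fit without 1 array. Without the 3 h cadmium array 1, calls of Ccng1 (adjusted p = 0.105), Zmat3 (0.126), Uqcc3 (0.162), Ccnd1 (0.105), Slc30a1 (0.120) and Atf6 (0.120) ended. Without array 3 of either 3 h group, calls of Ccng1 (0.0954), Zmat3 (0.140), Uqcc3 (0.101), Ccnd1 (0.106) and Slc30a1 (0.0947) ended, and without the 3 h cadmium array 2 those of Zmat3 (0.0587), Uqcc3 (0.0567), Ccnd1 (0.0517) and Atf6 (0.0759). Without array 3 of either 12 h group, calls of Zmat3 (0.193), Uqcc3 (0.103), Ccnd1 (0.0653), Slc30a1 (0.0564) and Atf6 (0.103) ended. Without the 12 h cadmium array 2, those of Uqcc3 (0.0926), Slc30a1 (0.0548) and Atf6 (0.0589) ended, and without the 12 h PBS array 2 that of Uqcc3 (0.0581). Over all alternatives the adjusted p ran from 2.46e-08 to 0.0171 for Mt2, 3.71e-05 to 0.125 for Cdkn1a, 0.000360 to 0.321 for Phlda3, 0.000539 to 0.428 for Nek7, 0.000180 to 0.599 for Ccng1, 0.00444 to 0.639 for Zmat3, 0.00237 to 0.827 for Uqcc3, 0.00151 to 0.622 for Ccnd1, 0.00368 to 0.599 for Slc30a1 and 0.00463 to 0.599 for Atf6. Of 72 splits, 4 called as many in mesoderm (38 in the real split, 60 at the highest other) and 15 in ectoderm (1 against 154). Some of the splits keep the real grouping at 1 time and so carry the cadmium effect. The splits thus do not decide about chance, which is not excluded for either count.

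Differences that called 0 genes in limma were likewise matched by all 72 splits, which by itself says nothing about chance. For cadmium between tissues the highest other split called 2 at 3 h (68 genes at an unadjusted p under 0.05) and 379 at 12 h (114). For acetazolamide it called 44 between tissues at 3 h (140), 2 between tissues at 12 h (230), 218 between times in ectoderm (261) and 2 between times in mesoderm (190). The counts of 379 and 218 point to a structure of the samples, whose cause was not tested.

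The effects of cadmium and acetazolamide in 12 h ectoderm had r = -0.46 across genes, which are not independent replicates (rho = -0.50). The largest axis of difference between vehicle arrays held 39.4% of the variance of their 8 differences. The cadmium arrays of this comparison differed from their vehicle arrays by 13.6 on it and the acetazolamide arrays by -17.2. With the scores of that axis as a covariate, taken from the 6 vehicle differences outside 12 h ectoderm (44.0% of their variance), r was -0.14. A candidate explanation is part of the variation that also separates vehicle arrays. The state of the RNA or the stage of the pooled litters could be its source, and these were not told apart. The covariate removes any effect along the axis, also one of the agents. The Gapdh 3' to 5' ratio was higher after both agents (0.49 and 0.41), where the axis scores were opposite. The cadmium value was -0.14 without cadmium array 2, so this ratio does not decide. Opposite action of the agents on single genes stays open and cannot be told apart from variation along the axis. In the agent difference limma called 0 genes, while 963 had an unadjusted p under 0.05. Chance cannot be excluded for r, since 26 of 72 splits gave an r as far from 0 (highest other 0.70).

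The lower Mt2 RNA 12 h after cadmium is the second pattern weighed. A single deviating array is argued against: the difference in mesoderm ran from -3.10 to -2.52 over the fits without 1 array. A fault of the Mt2 probe set alone would not lower Mt1, which was lower in mesoderm with an upper 95% bound of -0.47. This test was chosen after the Mt1 result was seen, so its outcome was not open. Mt1 fell by less than Mt2 (-0.76 against -2.86), and in 12 h ectoderm it was -0.22 beside -1.49. A part of the probe set in the size of the Mt2 fall is thus not excluded. Less metal-dependent transcription may have lowered 3 genes in mesoderm, Mt2, Mt1 and Slc30a1. The last, another target of the metal-responsive transcription factor, had an upper bound of -0.0872 there (estimate -0.22). Such lower transcription is a hypothesis from the same data, and Slc30a1 passed over its list alone and not over all genes (adjusted p = 0.0715). Mt1 and Mt2 also stood in the list of glucocorticoid-responsive genes, which did not pass as a list. These readings were not told apart. Metallothionein was not measured between 3 h and 12 h, and an earlier rise was not tested.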

How the results depend on the processing

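Tests under no weights, the original design, weights without the denominator block, median-centred arrays, the vehicle axis covariate, the first and second arrays, the arrays without the highest Gapdh ratios, separate probe sets, tissue averages and the 3' to 5' ratio covariate were chosen after the results were seen, and the others were planned. Quantile normalization, pseudocounts, a filter on dim probe sets, an intensity trend and the brightest probe set were not run, because ratios hold no intensity. For the same reason signal over background cannot be given. The weights themselves were chosen after counts without weights had been seen, and the simulated noise behind that choice held no correlation between genes. That noise was also scaled by the weights, so the simulation is no independent ground for them. Among the named results that were run again, 0 counted as reversed under any alternative. Others counted as moved: 29 with single arrays left out and 7 with only the first and second arrays. A further 6 moved with the vehicle axis covariate and 2 with arrayWeights. A change of sign in named genes that were not called is thus not excluded. These counts may leave out some genes named in the closing section.

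In 12 h cadmium mesoderm, Mt2 had adjusted p from 5.57e-11 to 0.119 over the alternatives, Mt1 from 6.21e-05 to 0.155, Cdkn1a from 1.09e-07 to 0.119, and Ccng1 from 2.85e-07 to 0.131. The upper ends come from fitting only the arrays compared, where few degrees of freedom are left. Mt2, Mt1, Cdkn1a, Ccng1, Phlda3 and Zmat3 passed in every fit without 1 array. Over 302 named results, 25 calls ended and 4 began without weights, 12 and 4 with median-centred arrays, and 8 and 1 with the axis covariate. With only the first and second arrays 59 ended and 3 began, and with only the arrays compared 69 and 0. A call can end only where the main fit made it. Only a part of the 302 results were called there, so 302 is not the base for the ended calls.

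Without weights 89 genes were called in 12 h cadmium ectoderm, 22 in 12 h cadmium mesoderm (all 22 among the 188), 1 in 3 h and 1 in 12 h after acetazolamide (mesoderm and ectoderm), 297 in the 12 h ectoderm agent difference and 1 in the cadmium time difference of mesoderm. By construction 1 shared spread is too small for the noisiest comparison and too large for the quietest. With group means and neither block nor weights, the original design, the counts were 112 in 12 h cadmium ectoderm, 34 in 12 h cadmium mesoderm, 16 in 12 h acetazolamide ectoderm, 356 in the 12 h ectoderm agent difference, and 13 and 1 in the cadmium time differences of ectoderm and mesoderm. With weights and without the denominator block, the counts were 8 in the 12 h ectoderm and 2 in the 12 h mesoderm agent difference and 62 in the cadmium time difference of mesoderm. Apart from mean effects, all other counts stayed within 1.5 times, 12 h cadmium mesoderm at 190, and 1 call of a named gene ended, that of Pfkp (adjusted p = 0.0668). With a replicate block, 5 genes were called in 3 h acetazolamide ectoderm. The block changed no other count over 1.5 times, and with a block pairing the tissues limma called 0 in all 4 tissue differences (88 and 173 at an unadjusted p under 0.05 for cadmium, 186 and 313 for acetazolamide). The cause was not tested.

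With arrayWeights (0.0358 to 13.5 per array, with a warning on convergence) 510 genes were called in 3 h and 483 in 12 h cadmium ectoderm, 5 in 3 h cadmium mesoderm, 9 in 3 h and 1261 in 12 h acetazolamide mesoderm. The agent differences had 2 in 3 h ectoderm, 1444 in 12 h ectoderm and 299 in 12 h mesoderm. The tissue differences had 2 and 6 for cadmium and 1 and 280 for acetazolamide at 3 h and 12 h. The time differences had 174 and 116 for cadmium and 1 and 57 for acetazolamide in ectoderm and mesoderm. The correlation of the agents in 3 h mesoderm reversed to -0.0367. The cause was not tested.

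With median-centred arrays 1 gene was called in 12 h cadmium ectoderm, 8 in 3 h acetazolamide ectoderm and 24 in the cadmium time difference of mesoderm. Mt1 and Mt2 stayed lower there in 12 h cadmium mesoderm. With the vehicle axis covariate 5 were called in 3 h acetazolamide mesoderm, 2 in the 12 h mesoderm agent difference and 58 in the cadmium time difference of mesoderm. The count in 12 h cadmium mesoderm was 217, of which 171 were among the 188. With both arrays of the highest Gapdh ratio left out, 5 were called in 12 h cadmium ectoderm, 1 in 3 h acetazolamide mesoderm, 11 in the 12 h mesoderm agent difference and 2 in the cadmium time difference of ectoderm, and r in 12 h mesoderm reversed to -0.12. With each probe set tested separately, 2 were called in the 12 h mesoderm agent difference and 3 in the cadmium time difference of ectoderm. The cause was not tested for any of these.

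With only the first and second arrays, 0 genes were called in limma in 12 h cadmium ectoderm (72 at an unadjusted p under 0.05), 29 in 12 h cadmium mesoderm, 28 in 3 h acetazolamide ectoderm, 1 in 3 h acetazolamide mesoderm and 3 in 12 h acetazolamide ectoderm. The 3 h ectoderm agent difference had 0 (566), and the cadmium time differences 0 in ectoderm (126) and 1 in mesoderm. The correlation of the agents in 3 h ectoderm reversed to 0.0876, and the cause was not tested. With only the arrays compared, limma called 0 in 12 h cadmium ectoderm (344 at an unadjusted p under 0.05) and mesoderm (988), in 3 h acetazolamide ectoderm (460) and mesoderm (785), in the 3 h ectoderm (503) and 12 h mesoderm (338) agent differences and in the cadmium time difference of ectoderm (332), and 1 in that of mesoderm. Of the 27 list calls, 2 passed with an estimated correlation. By fry 5 list tests passed, a count that does not compare directly, because fry tests a list against no change and camera against the other genes.

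Leaving out 1 array at a time gave these ranges, and the cause was not tested. Leaving out array 3 of either group also empties the second denominator. Counts for cadmium ran from 0 to 96 in 3 h ectoderm, 0 to 13 in 3 h mesoderm, 0 to 90 in 12 h ectoderm and 58 to 361 in 12 h mesoderm. Counts for acetazolamide ran from 2 to 78 in 3 h ectoderm, 0 to 141 in 3 h mesoderm and 0 to 338 in 12 h ectoderm, and stayed 0 in limma in 12 h mesoderm. The agent differences ran from 1 to 5 and 0 to 2 at 3 h, and 0 to 255 and 1 to 10 at 12 h, in ectoderm and mesoderm. In 12 h ectoderm the agent difference had 255 without PBS array 1, 168 without oil array 2, 5 without cadmium array 2, 2 without oil array 1 and 1 without array 3 of either acetazolamide or oil. In 12 h mesoderm it had 10 without acetazolamide array 2, 3 without acetazolamide array 1, 4 without cadmium array 1 and 2 without cadmium array 2. In 3 h ectoderm it had 5 without PBS array 2, 3 without cadmium array 1, and 2 without oil array 2 or array 3 of either acetazolamide or oil. In 3 h mesoderm it had 2 without array 3 of either cadmium or PBS and 1 without oil array 1. The tissue difference ran from 0 to 2 for cadmium at 12 h (2 without the ectoderm PBS array 1) and 0 to 1 for acetazolamide at 12 h (1 without array 3 of either ectoderm group). The time differences ran from 0 to 22 in ectoderm (22 without the 12 h PBS array 1, 2 without the 12 h cadmium array 2, 0 without the 3 h cadmium array 2 or array 3 of either 12 h group) and 5 to 95 in mesoderm for cadmium, and 0 to 1 in ectoderm for acetazolamide (1 without array 3 of either 12 h group). The correlations ran from -0.33 to 0.27 in 3 h ectoderm, -0.0878 to 0.48 in 3 h mesoderm, -0.58 to -0.17 in 12 h ectoderm and -0.12 to 0.26 in 12 h mesoderm. Signs reversed without array 3 of PBS or cadmium in 3 h ectoderm (0.27), without PBS array 1 in 3 h mesoderm (-0.0878), and without oil array 2 (-0.0677) or acetazolamide array 2 (-0.12) in 12 h mesoderm. The list calls ran from 24 to 34.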

Other observations

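The splits of arrays were planned, while the mean effects over several comparisons, their fits and splits on tissue averages, the 3' to 5' ratio covariate with the sizes of effects under it, the fit without the denominator block and the test of lower body temperature were chosen after the results were seen. A planned test on Rbm3 could not be run, because 0 probe sets name that gene alone, and the heat shock list took its place. Genes named in this part were chosen after their values were seen.

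Averaged over both agents and both tissues, 47 genes changed at 3 h, of which 34 were higher and 13 lower (991 at an unadjusted p under 0.05), and 43 had 1 sign in all 4 comparisons. Selection on the mean of these comparisons itself favours 1 sign, and the share over all genes was not computed. The 43 are thus no separate support. Cirbp, which encodes a cold-inducible RNA-binding protein, was higher by 0.86 ± 0.12 (adjusted p = 0.000990), and the forkhead gene Foxp1 by 0.27 ± 0.05. Atf6 was higher by 0.28 ± 0.05. Of 30 measured genes of the unfolded protein response list 2 were called, Xbp1 (-0.57 ± 0.11) and Herpud1 (-0.29 ± 0.06), and the list did not pass (median -0.0226, adjusted p = 0.762, and adjusted p = 0.939 with an estimated correlation). Of 20 heat shock genes 1 was called, Dnajb1 (-0.48 ± 0.09). Of 22 oxidative stress genes 2 were called, Me1 (0.31 ± 0.07) and Sqstm1 (0.26 ± 0.06), and that list did not pass (adjusted p = 0.0968, and adjusted p = 0.373 with an estimated correlation). Cirbp, Foxp1, Atf6, Xbp1 and Dnajb1 passed in every fit without 1 array. With only the first and second arrays Cirbp (adjusted p = 0.0583, the highest over its alternatives from 4.08e-07), Xbp1 (0.0831, from 0.00170) and Dnajb1 (0.0986, from 0.000117) did not pass, nor did Xbp1 with only the arrays compared (0.0547). The counts ran from 24 without the 3 h mesoderm acetazolamide array 1 to 129 without array 3 of either 3 h ectoderm cadmium or PBS. Counts were also over 1.5 times higher without array 2 of the mesoderm PBS (119) or oil (109) group or array 3 of either ectoderm acetazolamide or oil group (77). They were over 1.5 times lower without ectoderm PBS array 1 (31), ectoderm cadmium array 1 (27) or 2 (28), ectoderm oil array 1 (29), ectoderm acetazolamide array 1 (31) or 2 (27), mesoderm cadmium array 1 (31) or 2 (26), or mesoderm acetazolamide array 2 (25). The count was 16 without weights, 24 in the original design, 147 with arrayWeights, 76 with median-centred arrays, 79 with the vehicle axis covariate, 31 with only the first and second arrays and 29 without both arrays of the highest Gapdh ratio. It stayed within 1.5 times with a replicate block (52), with only the arrays compared (34), with separate probe sets (67) and with the 3' to 5' ratio covariate (33). It was 56 with weights and no denominator block. Lists passed at 3 h with the preset correlation and not with an estimated one: surface ectoderm (higher, median 0.0855, adjusted p = 0.0159 and 0.539), endoderm (lower, -0.0763, 0.0159 and 0.765) and the BMP pathway (lower, -0.0846, 0.0408 and 0.373). A difference in the share of cell types was not tested as a source of the 47. Over splits of all arrays, 1 of 100, the real one, called 47 genes, and the highest other called 4. Those splits treat the tissues as independent. With ectoderm and mesoderm averaged within each array number, 13 genes were called (896 at an unadjusted p under 0.05), Cirbp, Foxp1, Atf6, Xbp1 and Dnajb1 among them, and 1 of 72 splits, the real one, called as many (highest other 7). If the denominators are as inferred, the share of splits calling as many was under 0.05 for both counts. Both counts come from the same arrays, and this mean effect was chosen after the data were seen. No adjustment was made for the number of split tests, so chance is not excluded. The size of the count depends on the fit.

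Lower body temperature of the treated dams might raise Cirbp and lower heat shock genes at 3 h under both agents. The heat shock list gave p = 0.295 with an estimated correlation (p = 0.0743 with the preset one, median -0.03, 13 of 20 genes below 0), so the test leaves this open. No temperature is given in the labels, and handling or a general stress of the dam was not tested.

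Averaged over tissues and times, acetazolamide raised 59 genes and lowered 2 (1164 at an unadjusted p under 0.05), and 54 of the 61 had 1 sign in all 4 comparisons. Here too the selection favours 1 sign, and the share over all genes was not computed. D430019H16Rik was higher by 0.60 ± 0.07 (adjusted p = 2.00e-05) and passed under every alternative run (adjusted p up to 0.0153). Its calls were not limited to acetazolamide. It was also called in 12 h cadmium mesoderm, where 6 of 16 alternatives ended the call. The means of both agents called it at 3 h (ended by 1 of 36 alternatives) and at 12 h (3 of 36). The forkhead gene Foxo3 was higher by 0.58 ± 0.12, the antiproliferative gene Btg1 by 0.56 ± 0.12, the metabolic kinase gene Pdk1 by 0.59 ± 0.14 and the p53 target Zmat3 by 0.43 ± 0.08. The p53 list was higher (adjusted p = 0.00289, and adjusted p = 0.0216 with an estimated correlation), with 1 of its 15 members called. List tests of all mean effects treat the tissues as independent and were not run on tissue averages. Other lists passed with the preset correlation and not with an estimated one: mitosis (higher, adjusted p = 0.000371 and 0.423), hypoxia and glycolysis (higher, 0.000371 and 0.770), endothelium (lower, 0.0309 and 0.770), white blood cells (lower, 0.0321 and 0.821) and endoderm (lower, 0.00966 and 0.821). Over splits of all arrays, 1 of 100, the real one, called 61, and the highest other called 0, but those splits treat the tissues as independent. With the tissues averaged within each array number, 5 genes were called (960 at an unadjusted p under 0.05), and 2 of 72 splits called as many (highest other 1357). That share is under 0.05, but another split called 1357, which may come from a kept real grouping at 1 time or from a structure of the samples. These were not told apart, so the count of 61 is not taken as secured. With the mean of the Gapdh and actin 3' to 5' ratios as a covariate, 5 genes were called as well, D430019H16Rik and Zmat3 among them. This mean was higher in acetazolamide arrays of all 4 comparisons, though in 12 h mesoderm only through acetazolamide array 2 (-0.0106 without it). The effects of the 61 genes kept their sign there and 65.9% to 119% of their size (median 91.4%), while the SE grew to a median of 114%. The lost calls are thus no evidence that RNA quality was the source, and the lists were not tested in that fit. Nor do the kept effects exclude RNA quality, because the covariate holds only 2 control ratios and itself differed between acetazolamide and oil arrays. The count was 105 without weights, 136 in the original design, 112 with arrayWeights, 92 with weights and no denominator block, and 19 with only the first and second arrays. It stayed within 1.5 times with median-centred arrays (88), without both arrays of the highest Gapdh ratio (51), with only the arrays compared (70), with a replicate block (83) and with separate probe sets (81). With the vehicle axis as a covariate 19 genes were called, 16 of them among the 61, and Foxo3 (adjusted p = 0.111) and Zmat3 (0.0650) did not pass. Without the 12 h ectoderm acetazolamide array 1 the count was 9, and Foxo3 (0.0734) and Zmat3 (0.0620) did not pass. The Foxo3 call also ended without the 3 h mesoderm acetazolamide array 2 (0.0571; 14 genes called) or the 12 h mesoderm oil array 1 (0.0598; 12). On tissue averages Foxo3 (0.0740) and Zmat3 (0.0809) did not pass, nor did Foxo3 with the 3' to 5' ratio covariate (0.107). Over all alternatives the adjusted p ran from 0.00519 to 0.152 for Foxo3 and from 0.00613 to 0.0866 for Zmat3. The count was 33 without the 3 h ectoderm acetazolamide array 2, 40 without the 3 h mesoderm acetazolamide array 1, 37 without array 3 of either 12 h ectoderm group, 32 without array 3 of either 12 h mesoderm group, 94 without the 3 h mesoderm oil array 2 and 206 without the 12 h ectoderm oil array 2.

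Averages at 12 h called 20 genes over both agents and tissues (464 at an unadjusted p under 0.05) and 88 for cadmium over both tissues (1032). Cdkn1a (0.80 ± 0.15) and Ccng1 (1.04 ± 0.20) passed in the first, and Mt2 (-2.17 ± 0.23) in the second. The first 2 values come mostly from cadmium: its mean effect was 1.34 for Cdkn1a and 1.87 for Ccng1, against 0.35 and 0.15 for Cdkn1a and 0.38 and 0.06 for Ccng1 after acetazolamide in ectoderm and mesoderm. Their adjusted p over all alternatives ran from 1.16e-05 to 0.499 for Cdkn1a, from 0.000192 to 0.370 for Ccng1 and from 9.01e-08 to 0.0529 for Mt2. The Cdkn1a call ended with only the first and second arrays (0.499), with only the arrays compared (0.0507), on tissue averages (0.0807) and without the ectoderm array 3 of PBS or cadmium (0.103). The Ccng1 call ended with the first 3 of these (0.370, 0.0780 and 0.0715), with median-centred arrays (0.0506), and without the ectoderm cadmium array 1 (0.0629) or acetazolamide array 1 (0.0622). The Mt2 call ended with only the arrays compared (0.0529). Chance cannot be excluded for either count. Of 100 splits 5 called at least 20 (highest other 924), and of 72 splits 4 called at least 88 (highest other 379). Splits can keep the real grouping of single comparisons and so carry an agent effect, so these shares do not decide about chance. The highest values may come from that or from a structure of the samples, which were not told apart. On tissue averages limma called 0 over both agents (414 at an unadjusted p under 0.05), which all 72 splits match by definition (highest other 876), and 60 for cadmium, where 1 of 6 splits called as many (highest other 7), too few to exclude chance. The counts over both agents and for cadmium were 36 and 179 without weights, 50 and 207 in the original design, 160 and 1263 with arrayWeights, 12 and 73 with median-centred arrays, 40 and 73 with the vehicle axis covariate, and 78 and 373 without both arrays of the highest Gapdh ratio. They were 0 in limma (261 at an unadjusted p under 0.05) and 14 with only the first and second arrays, and 1 and 0 (865) with only the arrays compared. With a replicate block they were 23 and 99, with separate probe sets 20 and 97, with the 3' to 5' ratio covariate 18 and 88, and with weights and no denominator block 35 and 132. Lists passing with an estimated correlation were p53 targets in both means (higher, adjusted p = 2.70e-05 and 0.00753) and metallothionein and metal transport for cadmium (lower, 0.0286). With the preset correlation alone, metallothionein and metal transport, heat shock and cholesterol synthesis (lower) and hypoxia and glycolysis (higher) also passed over both agents, and mitosis and cholesterol synthesis (lower) and endothelium (higher) for cadmium. Over single arrays left out, the counts ran from 9 (12 h ectoderm cadmium array 1) to 65 (12 h ectoderm cadmium array 2) and from 21 (array 3 of either 12 h ectoderm cadmium or PBS) to 456 (12 h ectoderm cadmium array 2).

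For single agent comparisons the arrays allow 6 splits within their denominators, too few for a share under 0.05. In 12 h cadmium mesoderm 1 of 6 called as many (188 in the real split, 19 at the highest other), and in 12 h cadmium ectoderm 2 of 6 (2, and 7 at the highest other). After acetazolamide 1 of 6 did in 3 h ectoderm (2, and 0 at the highest other) and 1 of 6 in 3 h mesoderm (3, and 0). In the comparisons where limma called 0 genes, all 6 of 6 did, with 0 at the highest other: cadmium at 3 h in ectoderm (274 at an unadjusted p under 0.05) and mesoderm (256), and acetazolamide at 12 h in ectoderm (649) and mesoderm (65).

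For the correlations of the agents across genes, chance cannot be excluded either: 46 of 72 splits gave an r as far from 0 in 3 h ectoderm (real -0.16, highest other -0.70), 44 in 3 h mesoderm (0.28, -0.55) and 40 in 12 h mesoderm (0.08, 0.51). For the 27 list calls it cannot be excluded, since 21 of 100 splits gave as many (highest other 35). Among the probe sets without a single named gene, 13 of 1633 were called in 12 h cadmium mesoderm and 0 by limma in the other comparisons.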
